A study of Mus musculus with 8 samples.

How the data were processed

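Total RNA from the livers of 8 male C57BL/6N mice, 4 fed regular diet and 4 fed a NASH-inducing diet for 12 weeks, was measured on Affymetrix whole-transcript arrays, 1 array per mouse. Per the labels' protocols, RNA was extracted with a spin-column kit, and 300 ng were amplified and biotin-labelled with whole-transcript kits. The values used are the authors' processed log2 expression values, with 1 value per probe set and array. Probe sets are defined by gene identifier, so that each gene has 1. How the authors summarised, background-corrected and normalized the probes is not given in the sources used here. That the deposited values are on a log2 scale follows from the data: they run from about 5 to 13, and differences of diet means equal the authors' listed log2 fold changes to within 5.03e-05 for every listed gene. Quartiles were close but not identical between arrays, so the probe set values themselves were not forced onto 1 distribution. Whether the probes were before they were summarised cannot be told from this. The authors' deposited table of changed genes gives a mean log2 expression, a log2 fold change (NASH-inducing minus regular diet) and a false discovery rate (an adjusted p-value) per gene, with the authors' test not given in the sources used here. Its largest listed value is 0.0499.

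The deposited log2 values were used as they stand, with no filter on dim probe sets and no further normalization. Normalized values carry no call of signal above background, so no gene is called present or absent, and folds of genes near the lowest signals are compressed. Gene symbols were looked up by gene identifier in a RefSeq gene table of GRCm38.p6, used for names only, and no coordinates are given. Of 21212 probe sets, 20656 were named and 556 were not. Of the 3012 genes with a symbol in both this table and the authors', 2741 had the same symbol, 254 an older symbol of the same gene and 17 another.

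Groups were taken from the diet named in the labels. Each log2 value was fitted on diet alone in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, the tests of single genes were two-sided, and p-values were adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05. Fold changes are NASH-inducing over regular diet. Every adjusted p of a single gene is from this fit unless another is named. Jun was also tested with an exact two-sided permutation test of the difference of means over the 70 allocations. Gene lists were tested with limma's camera at its preset correlation of 0.01 and adjusted over the 43 lists, and every adjusted p of a list is camera's unless another is named. Camera with a correlation estimated from the data and fry were run as alternatives. The lists, with 988 entries, were fixed from textbook knowledge before the data were examined. Of the entries, 953 were matched by symbol, 7 by an older symbol and 28 were not measured, leaving 892 distinct genes. Some genes stand in more than 1 list.

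The genes named in the text follow a rule fixed before the data were examined. It takes every measured AP-1 family gene, and the 10 largest rises and 10 largest falls among genes past the threshold whose diets do not overlap, leaving out unnamed predicted genes. For each list past the test it takes up to 4 members past the threshold with the largest change and up to 2 against the list's direction, and for other lists the 2 with the smallest adjusted p. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen. Probe sets of near-identical genes (Cyp2b, Cyp2c, Cyp3a, Cyp4a, Acot, Mup, Saa, Orm, H2, Sult2a, Gsta, Gstm and C4 genes) can share probes, and their changes are uncertain for that reason.

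Checked on simulated data with the spread of these arrays and 200 of 21212 genes changed, the fit recovered 92.5% of genes changed by 0.5 on the log2 scale, 97.0% of those changed by 1 and 100% of those changed by 2. False calls made up 8.53% of calls, and no gene was called when none was changed. The list test found 5 of 5 lists shifted by 0.5 and none when no gene was changed, and with an estimated correlation it also found 5 of 5. The simulated genes were drawn independently of each other, so this does not check the list test for genes that move together. On the real arrays, another split of the mice passed as many as 29 lists at the preset correlation. Such a split exchanged only NASH-diet replicate 1 with a regular-diet mouse, so it kept much of the diet difference. Splits with equal numbers of each diet in both groups passed 4 to 17 lists. Alternatives were quantile normalization, centring of each array on the median of the probe sets of intermediate mean signal (between the quartiles), removal of probe sets below the 25th or 50th percentile of mean signal, a trended and robust prior variance, array weights, the replicate number as a block, other thresholds, and leaving out each mouse in turn. Added after seeing the data were a fit of Jun with the immediate early genes as a covariate, the count of the authors' listed genes with array weights, list counts without NASH-diet replicate 1, gene families by symbol root, and the position of each NASH-diet mouse, against the other 3 or against replicates 2 and 3 alone. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).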

Results

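Hepatic gene expression was measured on 8 single-channel Affymetrix whole-transcript arrays, each hybridised with liver RNA from 1 male C57BL/6N mouse. From 14 weeks of age, 4 mice received regular diet and 4 received a diet made to induce nonalcoholic steatohepatitis (NASH), the inflammatory form of fatty liver disease. Livers were taken after 12 weeks of diet, at 26 weeks of age. Each mouse is a replicate (n = 4 per diet). The comparison asks which hepatic genes differ between the diets, and the series title points to Jun, which encodes the transcription factor c-Jun. The array carries 1 probe set per gene, 21212 in all, and 20656 of these could be named. Array medians ran from 5.87 to 5.99 on the log2 scale. A median probe set had a mean of 5.93, close to the lowest values of about 5, so that changes of genes with low signal are understated. The number of arrays limits the precision: the median standard error (SE) of a log2 fold change was 0.0427.

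The 2 diets separated along the first principal component, which held 60.9% of the variance over all probe sets. Regular-diet livers scored between -14.8 and -11.9 on it, and NASH-diet livers between 6.12 and 19.4. NASH-diet replicate 1, at 6.12, lay nearest to the regular-diet livers. Correlations across genes were 0.994 to 0.996 between arrays of the same diet and 0.982 to 0.992 between arrays of different diets.

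**Figure D1:**
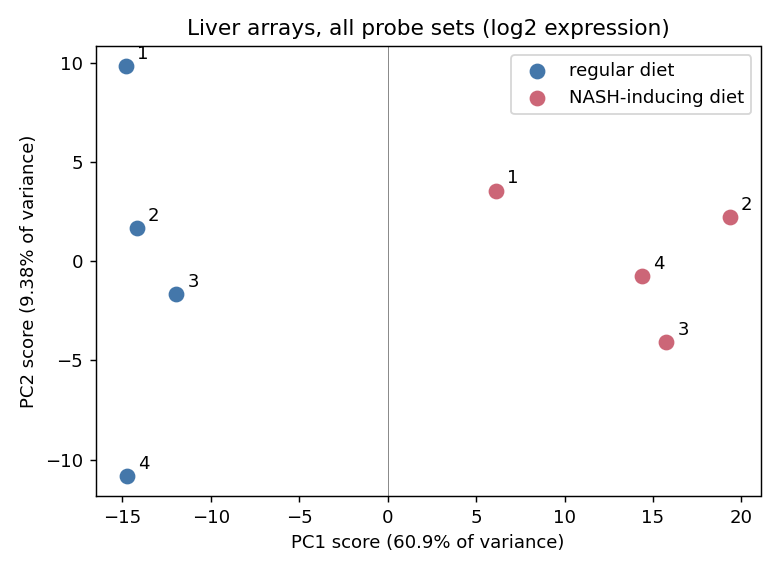
Scores of the 8 liver arrays on the first and second principal components of log2 expression over all probe sets, which hold 60.9% and 9.38% of the variance. Points are mice, coloured by diet and numbered by replicate. The NASH-diet mice lie between 6.12 and 19.4 on the first component and the regular-diet mice between -14.8 and -11.9.

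Livers on the NASH-inducing diet had higher expression of lipid droplet, fatty acid oxidation, extracellular matrix, macrophage and sinusoidal endothelial genes. They had lower expression of genes for amino acid breakdown, cholesterol synthesis, hepatocyte identity and male-biased liver enzymes. These gene lists passed camera at its preset correlation, and none of them passed with a correlation estimated from the data (lowest adjusted p = 0.198). In limma, 2688 of the 21212 probe sets passed an adjusted p of 0.05, which is 12.7% of those tested. Of these, 2052 were higher and 636 lower under the NASH-inducing diet. Most changes were small, with a median absolute log2 fold change of 0.30, and 106 probe sets (83 higher, 23 lower) reached an absolute value of 1. In 3744 probe sets all 4 mice of one diet lay above all 4 of the other, 17.7% against the 2.86% that chance gives. The split into higher and lower calls moved with the scaling of the arrays. It was 1415 higher and 1350 lower after quantile normalization, and 1346 higher and 1877 lower after centring each array on the probe sets of intermediate mean signal, which shifted the median of all probe sets by -0.06.

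Jun was higher in the livers of NASH-diet mice, at 9.96 ± 0.26 (SD, n = 4) against 8.60 ± 0.84 on the log2 scale in regular-diet mice. The difference of 1.37 ± 0.36 (SE) is 2.58-fold, with an adjusted p of 0.0398 in limma. All 4 NASH-diet values (9.64, 9.88, 10.10 and 10.23) lay above all 4 regular-diet values (7.47, 9.39, 8.49 and 9.04). The exact two-sided permutation test of the means gave p = 0.0286, the smallest that the 70 allocations of 8 mice allow. The regular-diet mice varied more than the NASH-diet mice, and without regular-diet replicate 1 the log2 fold change was 0.99, with adjusted p = 0.0258. The adjusted p rose above 0.05 without regular-diet replicate 3 (0.0940), NASH-diet replicate 2 (0.0868), NASH-diet replicate 3 (0.101) or NASH-diet replicate 4 (0.0981), and with a trended, robust prior variance (0.0794). With the mean of the immediate early genes as a covariate, the log2 fold change of Jun was 0.063 (SE 0.40, adjusted p = 0.977). That mean itself separated the diets, at 6.42 to 6.77 in regular-diet and 6.82 to 7.28 in NASH-diet mice. Adjusting for it also takes out change that follows diet, so this fit does not show that Jun is unaffected by diet.

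Of the 13 AP-1 family genes, whose products dimerise with or resemble c-Jun, 3 rose, also when adjusted over the list alone, and 10 did not pass. Besides Jun, Atf3 rose 2.45-fold (log2 fold change 1.29 ± 0.32 SE, adjusted p = 0.0329) and Fosl2 rose 1.20-fold (0.26 ± 0.07, adjusted p = 0.0417). The call of Atf3 was lost in 6 and that of Fosl2 in 7 of the 8 fits that left out 1 mouse. Fos (0.29), Jund (0.27), Junb (0.15), Jdp2 (0.11), Fosb (0.10), Batf2 (0.09), Batf (0.05), Fosl1 (0.03), Atf2 (0.02) and Batf3 (0.00) had log2 fold changes that did not pass, and those of Batf, Fosl1, Atf2 and Batf3 turned negative under another scaling. Most of these genes had means below 6 in regular-diet livers. As a list, the family was higher (camera, adjusted p = 0.00509), with adjusted p = 0.313 with an estimated correlation and 0.092 without the dimmest 50% of probe sets. Among 19 genes listed as AP-1 targets from textbook knowledge, 10 rose (13 adjusted over the list alone) and none fell, with camera's adjusted p = 4.91e-07 and adjusted p = 0.274 with an estimated correlation. They included the cyclin gene Ccnd1 (2.20-fold, log2 1.14 ± 0.12 SE), the intermediate filament gene Vim (2.17-fold, 1.12 ± 0.10) and the chemokine gene Ccl2 (1.81-fold, 0.85 ± 0.13). Only 4 of these 19 targets are in no other list, and those 4 did not pass camera together (adjusted p = 0.102). The rest are also counted in other lists, so this list is largely not separate from them. Of 21 other immediate early genes, 7 rose (8 adjusted over the list alone), led by Btg2 (3.29-fold, log2 1.72 ± 0.20 SE), Myc (2.21-fold, 1.15 ± 0.32), Klf6 (2.04-fold, 1.03 ± 0.18) and Ccn2 (1.50-fold, 0.59 ± 0.10). The call of Myc (adjusted p = 0.0497) was lost in 5 of the 8 fits without 1 mouse. Their list passed camera (adjusted p = 4.61e-05), with adjusted p = 0.313 with an estimated correlation.

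**Figure D2:**
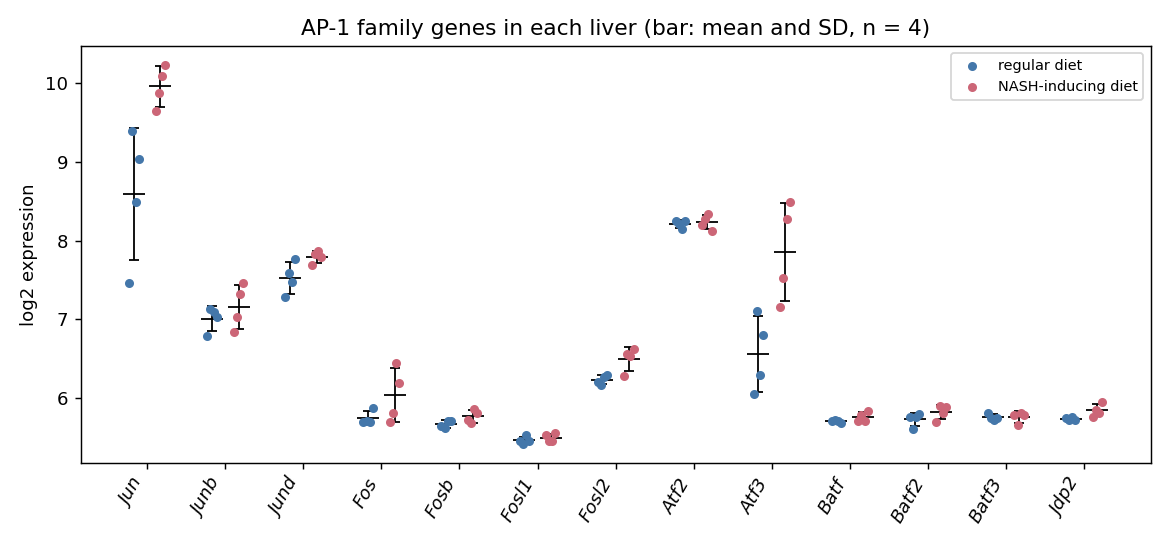
Log2 expression of the 13 AP-1 family genes in each liver. Points are mice on regular or NASH-inducing diet, and bars give the mean and SD of 4 mice. Jun reads 7.47 to 9.39 in regular-diet mice and 9.64 to 10.23 in NASH-diet mice, while Atf2, Fosl1, Batf and Batf3 differ by 0.05 or less between the diets, with a sign that flips under another scaling.

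The largest rise belonged to Cyp2b9, a cytochrome P450 gene that is normally higher in female than in male mouse liver. It rose 14.0-fold (log2 fold change 3.80 ± 0.43 SE, adjusted p = 0.00153), although probes can be shared with its close relatives such as Cyp2b10. Cidec and Cidea, whose proteins drive the growth of lipid droplets, rose 12.2-fold (3.61 ± 0.15, adjusted p = 3.53e-05) and 7.88-fold (2.98 ± 0.27, adjusted p = 0.000801). Rgs16, a regulator of G protein signalling, rose 7.14-fold (2.84 ± 0.37), and Lcn2, which encodes the siderophore-binding protein lipocalin 2, rose 6.15-fold (2.62 ± 0.27). Between 3.73-fold and 4.47-fold rises were measured for Abcd2, a peroxisomal fatty acid transporter, S100a11, the lysophospholipid transporter Mfsd2a, the pantetheinase Vnn1 and the annexin Anxa2. The largest fall was that of Hsd3b5, a male-specific steroid dehydrogenase gene, which fell by 3.39 ± 0.57 (SE) on the log2 scale, 10.5-fold (adjusted p = 0.0069). Hsd3b5 varied among NASH-diet mice, at 6.97 ± 1.36 (SD, n = 4) against 10.36 ± 0.34 in regular-diet mice. Clec2h was 3.57-fold lower and the complement gene C8b 3.25-fold lower. Adgrf1, the phospholyase gene Etnppl and the carboxylesterase gene Ces2a were each 3.14-fold lower. Slco2a1, a prostaglandin transporter, was 3.08-fold lower, Urad, an enzyme of urate breakdown, 2.77-fold, Cyp7b1, an oxysterol hydroxylase, 2.66-fold, and Susd4 2.52-fold. Each of these 20 genes had all 4 NASH-diet mice on one side of all 4 regular-diet mice, with adjusted p of 0.014 or less.

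**Figure D3:**
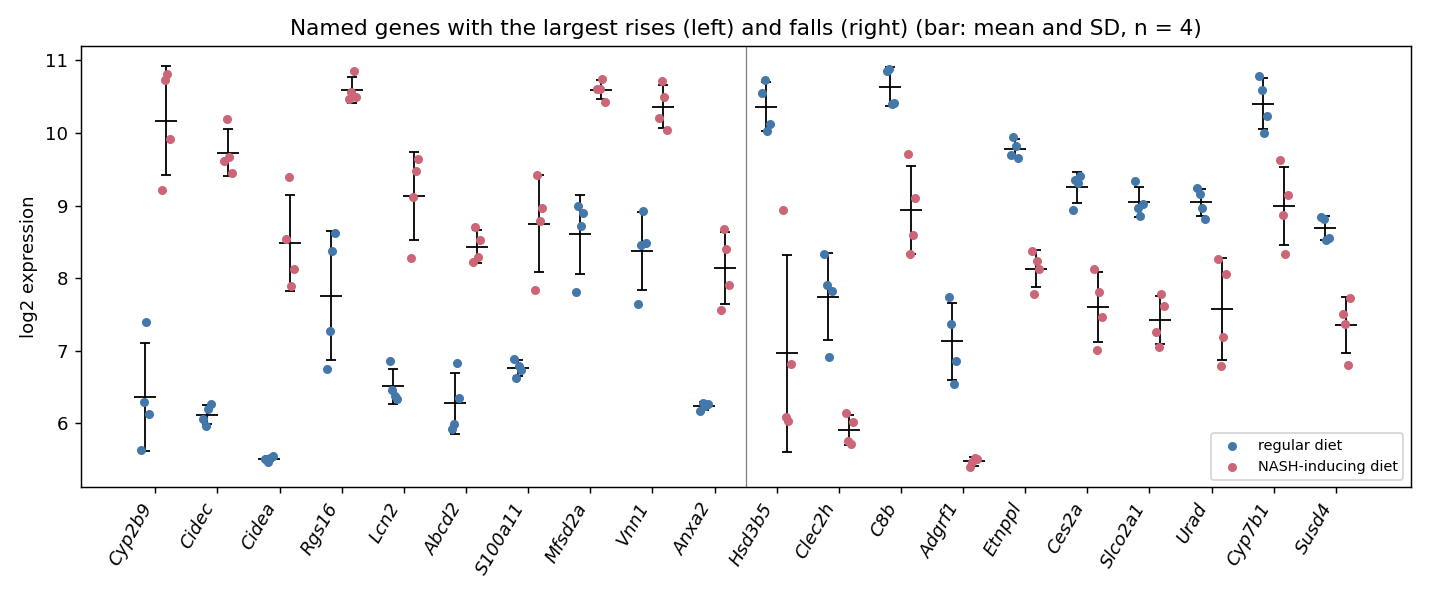
Log2 expression in each liver of the 10 named genes with the largest rises (left of the grey line) and the 10 with the largest falls (right). Points are mice, and bars give the mean and SD of 4 mice per diet. The diets do not overlap in any of the 20 genes, from Cyp2b9 (log2 fold change 3.80) to Hsd3b5 (-3.39).

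Genes of lipid storage and fatty acid use rose together. Of 34 PPAR-alpha targets and fatty acid oxidation genes, 23 rose (28 adjusted over the list alone) and none fell, with a median log2 fold change of 0.43. Camera gave this list an adjusted p of 2.37e-14, with adjusted p = 0.274 with an estimated correlation. Beside Vnn1, the acyl-CoA thioesterase gene Acot2 rose 2.86-fold (log2 1.52 ± 0.21 SE), the peroxisome proliferation gene Pex11a 2.64-fold (1.40 ± 0.11) and the carnitine acetyltransferase gene Crat 2.27-fold (1.18 ± 0.12). Acot2 has close relatives that can share its probes. Among 19 lipid droplet genes, 11 rose (14 adjusted over the list alone), including Plin4 (2.39-fold, 1.26 ± 0.14) and Fitm1 (1.93-fold, 0.95 ± 0.19), with camera's adjusted p = 4.58e-09 and adjusted p = 0.198 with an estimated correlation. Of 17 lipid uptake and PPAR-gamma target genes, 9 rose (12 adjusted over the list alone), with camera's adjusted p = 1.1e-07 and adjusted p = 0.198 with an estimated correlation. They included the uncoupling protein gene Ucp2 (2.83-fold, 1.50 ± 0.30), the apolipoprotein gene Apoa4 (2.78-fold, 1.48 ± 0.19), the fatty acid-binding protein gene Fabp2 (2.49-fold, 1.31 ± 0.13) and, chosen after its values were seen, Pparg itself (1.19). None of the members of these 3 lists fell.

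Genes of fatty acid and triglyceride synthesis did not move as a list (camera, adjusted p = 0.444). Of 29 measured, 4 rose (5 adjusted over the list alone) and 1 fell, with a median log2 fold change of 0.06, although the list passed after quantile normalization (adjusted p = 0.0177) and after centring (0.0334). The acyltransferase gene Mogat1 (1.85-fold, 0.89 ± 0.12 SE) rose. Chosen after their values were seen, Fasn (-0.29), Acly (-0.43) and Scd1 (-0.25) did not pass. Genes of cholesterol synthesis and uptake were lower: 8 of 24 fell (17 adjusted over the list alone), none rose, and the median log2 fold change was -0.41. Camera gave them an adjusted p of 1.35e-08, with adjusted p = 0.274 with an estimated correlation. Tm7sf2, a sterol reductase gene, was 1.89-fold lower (-0.92 ± 0.13), while the calls of Msmo1 (-0.81), Pmvk (-0.66) and Cyp51 (-0.78) were each lost in most fits that left out 1 mouse. Of 15 LXR target and sterol efflux genes, 4 rose (4 rose and 1 fell adjusted over the list alone), including the cholesterol exporter gene Abcg1 (1.48-fold, 0.56 ± 0.07) and Lpcat3 (1.32-fold, 0.40 ± 0.05), and camera gave an adjusted p of 0.192. Without NASH-diet replicate 1, 3 rose and 2 fell. That list passed after quantile normalization (0.0438) and after centring (0.0220).

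Genes of amino acid breakdown and hepatocyte identity fell. In the urea cycle and amino acid catabolism list, 23 of 34 fell (27 adjusted over the list alone) and 1 rose (2 adjusted over the list alone), with a median log2 fold change of -0.39. Camera gave an adjusted p of 3.22e-15, with adjusted p = 0.274 with an estimated correlation. Cth, which makes cysteine from cystathionine, was 2.34-fold lower (-1.22 ± 0.07 SE), the histidine lyase gene Hal 2.04-fold (-1.03 ± 0.13), the proline dehydrogenase gene Prodh 1.89-fold (-0.92 ± 0.18) and Cps1, the first enzyme of the urea cycle, 1.84-fold (-0.88 ± 0.13). The alanine aminotransferase gene Gpt2 moved the other way (1.34-fold higher, 0.43 ± 0.09), with its call lost in 1 of the 8 fits without 1 mouse. Of 23 hepatocyte identity genes, 15 fell (19 adjusted over the list alone) and none rose, with camera's adjusted p = 2.82e-13 and adjusted p = 0.274 with an estimated correlation. Their median log2 fold change was -0.26 as deposited, -0.13 after quantile normalization and -0.31 after centring. Ass1 (-0.47 ± 0.09) was among them, as was Tat (-0.55 ± 0.13), whose call was lost in 4 of the 8 fits without 1 mouse and after quantile normalization.

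Bile acid, complement and P450 genes moved both ways. Of 27 bile acid genes 8 fell and 2 rose (10 and 3 adjusted over the list alone), with camera's adjusted p = 0.0010 and adjusted p = 0.274 with an estimated correlation. The bile salt export pump gene Abcb11 was 1.84-fold lower (-0.88 ± 0.09 SE) and Akr1d1 1.75-fold lower (-0.81 ± 0.15), while the canalicular phospholipid exporter gene Abcb4 (1.54-fold, 0.62 ± 0.11) and Abcc3 (1.47-fold, 0.55 ± 0.11) rose. Of 25 complement genes 8 fell and 4 rose (11 and 5 adjusted over the list alone), with camera's adjusted p = 0.000253 and adjusted p = 0.274 with an estimated correlation. C9 (-0.68), C2 (-0.61) and C8a (-0.56) fell with C8b, while the properdin gene Cfp (0.73) and the receptor gene C3ar1 (0.59), both typical of leukocytes, rose. Of 36 genes of drug-metabolising P450s and their regulators 12 fell and 6 rose (17 and 9 adjusted over the list alone), with camera's adjusted p = 0.000491 and adjusted p = 0.274 with an estimated correlation. Cyp1a2 was 1.85-fold lower (-0.88 ± 0.11) and Cyp2c23 1.63-fold lower (-0.70 ± 0.11), against rises of Cyp2b9 and of Cyp2b10 (3.24-fold, 1.70 ± 0.23), families whose probes can be shared. The mean of the P450 list was -0.03 against a median of -0.18. Centring the arrays raised the test of all 3 lists above 0.05, with adjusted p = 0.0893 for bile acid, 0.0636 for complement and 0.169 for P450 genes.

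Male-biased and growth hormone-dependent genes were lower in the NASH-diet livers. Of 24 measured, 14 fell, also when adjusted over the list alone, and none rose (1 adjusted over the list alone), with a median log2 fold change of -0.61. Camera gave an adjusted p of 1.15e-10, with adjusted p = 0.274 with an estimated correlation. Hsd3b5, Ces2a, Cyp7b1 and Susd4 led the list. Of 17 female-biased genes, 6 rose (7 adjusted over the list alone), among them Cyp2b9 and Abcd2, and 1 fell (3 adjusted over the list alone). That list had a median log2 fold change of 0.00 and a mean of 0.46 and did not pass camera (adjusted p = 0.268), though it passed after quantile normalization (0.0374) and centring (0.0443), without the dimmest 25% (0.0188) or 50% (0.0451) of probe sets, and with fry's directional test (0.0427). The mean of 4 Y-linked genes was 7.38 to 7.50 in regular-diet and 7.39 to 7.58 in NASH-diet mice.

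Markers of several non-hepatocyte liver cells were higher. Of 16 sinusoidal endothelial markers, 13 rose (16 adjusted over the list alone), with a median log2 fold change of 0.38. Lyve1, a hyaluronan receptor, rose 2.31-fold (1.21 ± 0.12 SE), the cadherin gene Cdh5 1.49-fold (0.57 ± 0.08) and Pecam1 1.45-fold (0.53 ± 0.07). Camera gave an adjusted p of 4.96e-12, with adjusted p = 0.198 with an estimated correlation. Of 15 Kupffer cell markers 9 rose (11 adjusted over the list alone), with adjusted p = 2.84e-06 and adjusted p = 0.274 with an estimated correlation. The complement component genes C1qb (2.26-fold, 1.18 ± 0.18) and C1qc (1.95-fold, 0.96 ± 0.16) and the receptor genes Vsig4 (1.74-fold) and Adgre1 (1.64-fold) were higher. Of 20 markers of recruited and lipid-associated macrophages 15 rose (16 adjusted over the list alone), with adjusted p = 3.82e-09 and adjusted p = 0.274 with an estimated correlation. They included Cd68 (1.99-fold, 0.99 ± 0.17), the beta-glucan receptor gene Clec7a (1.80-fold, 0.84 ± 0.14), Mpeg1 (1.71-fold) and the cathepsin gene Ctss (1.69-fold). Over the same mice the hepatocyte identity genes had a median of -0.26.

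**Figure D4:**
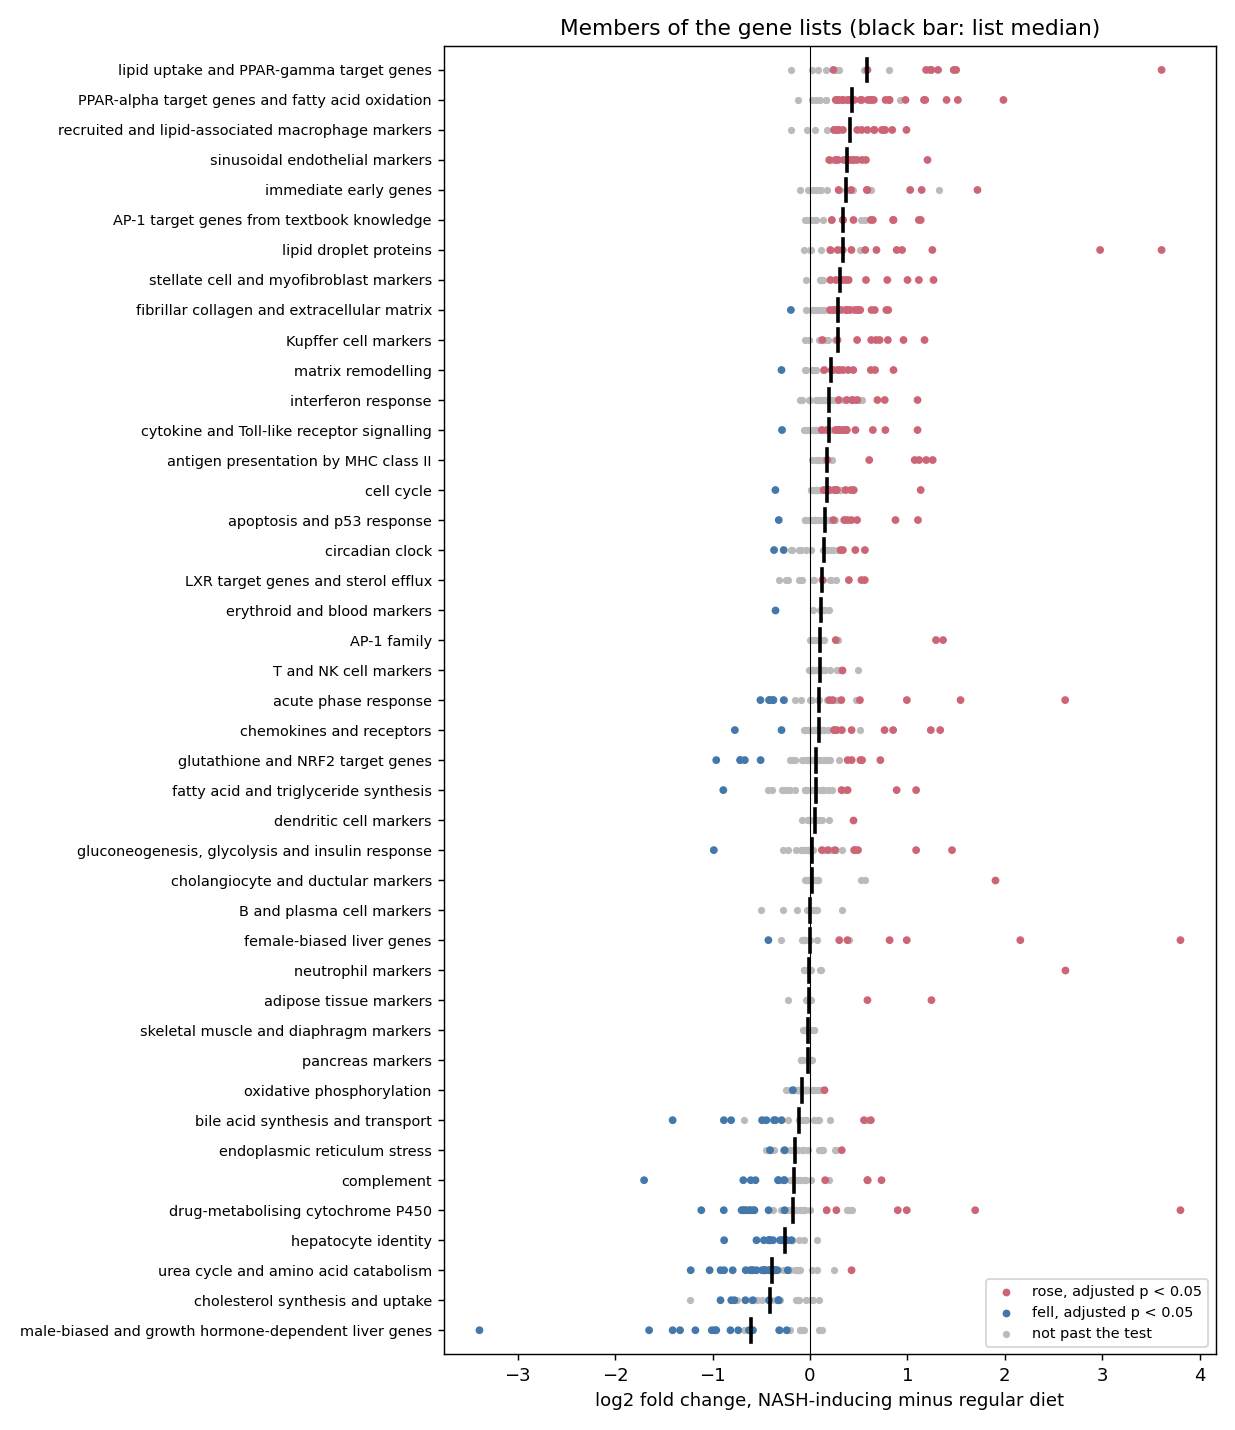
Log2 fold change (NASH-inducing minus regular diet) of every measured member of the 43 gene lists, sorted by list median (black bar). Red and blue points rose or fell with an adjusted p under 0.05, and grey points did not pass. Medians run from -0.61 for male-biased genes to 0.59 for lipid uptake and PPAR-gamma target genes, and the means of the erythroid and glutathione lists change sign under another scaling.

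Matrix and stellate cell genes rose moderately. Of 29 collagen and extracellular matrix genes, 19 rose (23 adjusted over the list alone) and 1 fell, with a median log2 fold change of 0.29. Camera gave an adjusted p of 3.98e-13, with adjusted p = 0.198 with an estimated correlation. Sparc rose 1.75-fold (0.80 ± 0.08 SE), Col14a1 1.72-fold (0.78 ± 0.06), Dpt 1.59-fold and Thbs1 1.55-fold. The main fibrillar collagen genes, chosen after their values were seen, gave log2 fold changes of 0.49 for Col1a1, 0.41 for Col1a2 and 0.39 for Col3a1, with adjusted p of 0.003 or less. Fn1 was 1.15-fold lower (-0.20 ± 0.05), a call lost after quantile normalization and in 6 of the 8 fits without 1 mouse. Of 18 stellate cell and myofibroblast markers, 11 rose (13 adjusted over the list alone), with adjusted p = 6.87e-09 and adjusted p = 0.198 with an estimated correlation. The matricellular gene Postn rose 2.41-fold (1.27 ± 0.13), Vim 2.17-fold and the smooth muscle actin gene Acta2, a marker of activated stellate cells, 1.73-fold (0.79 ± 0.13). Of 20 matrix remodelling genes 11 rose (12 adjusted over the list alone) and 1 fell, with adjusted p = 2.29e-05 and adjusted p = 0.274 with an estimated correlation. Adamts1 (1.59-fold) and the macrophage metalloproteinase gene Mmp12 (1.54-fold) rose, and Mmp19 was 1.22-fold lower (-0.29 ± 0.03).

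Immune signalling genes were higher. Of 33 cytokine and Toll-like receptor genes, 15 rose (22 adjusted over the list alone) and 1 fell, with adjusted p = 1.23e-07 and adjusted p = 0.274 with an estimated correlation. The receptor genes Tlr12 (2.15-fold, log2 1.10 ± 0.08 SE) and Tlr5 (1.71-fold, 0.77 ± 0.09) and the cytokine gene Tgfb1 (1.56-fold, 0.65 ± 0.09) rose, and Il18 was 1.22-fold lower (-0.29 ± 0.06), a call lost in 3 of the 8 fits without 1 mouse. Of 13 genes of MHC class II presentation, 6 rose (7 adjusted over the list alone), with adjusted p = 6.48e-06 and adjusted p = 0.274 with an estimated correlation. H2-Aa (2.40-fold, 1.26 ± 0.20), Cd74 (2.29-fold, 1.19 ± 0.19), H2-Eb1 (2.17-fold) and H2-Ab1 (2.11-fold) led them, and the H2 genes have relatives that can share probes. Of 33 interferon response genes 8 rose (15 adjusted over the list alone), with adjusted p = 4.08e-05, adjusted p = 0.437 with an estimated correlation and 0.0781 with fry's directional test. Ifi44 rose 1.62-fold (0.69 ± 0.10), and without NASH-diet replicate 1 the count of that list was 18. Of 29 chemokine and receptor genes 9 rose and 2 fell (12 and 2 adjusted over the list alone), with adjusted p = 0.0071 and adjusted p = 0.443 with an estimated correlation. That list did not pass without the dimmest 50% of probe sets (0.307), with fry's directional test (0.0614) or over its members found in no other list (0.121). Ccl2 rose, Ccl9 was 1.71-fold lower (-0.77 ± 0.09), and the rises of Cxcl9 (2.53-fold) and Ccl5 (2.36-fold) were lost in 5 and 6 of the 8 fits without 1 mouse. For T and NK cell markers 1 of 25 rose, also when adjusted over the list alone, namely Gzma (1.25-fold, 0.33 ± 0.06), and 4 rose without NASH-diet replicate 1, with adjusted p = 0.00189 for the list, adjusted p = 0.481 with an estimated correlation and 0.0926 with fry's directional test.

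Cell cycle genes shifted upward, with 12 of 35 higher (23 adjusted over the list alone) and 1 lower (Tk1, a call lost in 4 of the 8 fits without 1 mouse), at an adjusted p of 1.5e-08 and adjusted p = 0.313 with an estimated correlation. Ccnd1 and the proliferation marker gene Mki67 (1.37-fold, 0.45 ± 0.09 SE) rose, and without NASH-diet replicate 1 the count of higher genes was 22. Of 26 apoptosis and p53 response genes 7 rose and 1 fell (10 and 1 adjusted over the list alone, and 12 rises without NASH-diet replicate 1), with adjusted p = 0.000857, adjusted p = 0.274 with an estimated correlation and 0.0804 without the dimmest 50% of probe sets. Gadd45a (1.40-fold, 0.48 ± 0.09) and Casp8 (1.34-fold, 0.42 ± 0.07) rose. Oxidative phosphorylation genes had a median of -0.08, with 1 of 43 higher and 1 lower (0 adjusted over the list alone), adjusted p = 8.38e-05, and adjusted p = 0.481 with an estimated correlation. Without NASH-diet replicate 1 none of them was higher and 4 were lower, and fry's directional test did not pass (0.260), nor did its test of either direction (0.0901). Endoplasmic reticulum stress genes had a median of -0.15, with 1 of 27 higher and 2 lower, also when adjusted over the list alone. Ern1 (-0.41 ± 0.09) was the larger fall, and the list's adjusted p of 0.0234 compared with an adjusted p = 0.535 with an estimated correlation, 0.0732 after quantile normalization, 0.448 after centring and 0.359 with fry's directional test. It was 0.268 without regular-diet replicate 1, 0.0579 without NASH-diet replicate 2 and 0.0596 without NASH-diet replicate 4, and 1 gene was lower without NASH-diet replicate 1.

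In total, 28 of the 43 lists passed camera, 19 higher and 9 lower. None passed with an estimated correlation, where 5 had an unadjusted p under 0.05, while fry's directional test, which asks whether a list's own genes move one way, passed 25. Among lists that did not pass camera, 8 of 26 genes of glucose metabolism and insulin response rose and 1 fell (11 and 2 adjusted over the list alone), with adjusted p = 0.139. Igfbp2 was 1.98-fold lower there (-0.99 ± 0.09 SE), 3 were lower without NASH-diet replicate 1, and the list passed after quantile normalization (0.0144), after centring (0.00801) and with fry's directional test (0.0356). Of 32 glutathione and NRF2 target genes 5 rose and 5 fell (8 and 5 adjusted over the list alone), with adjusted p = 0.733. Gstp1 was 1.95-fold lower (-0.96 ± 0.10) and the sulfiredoxin gene Srxn1 1.65-fold higher (0.72 ± 0.12). Of 25 acute phase genes 7 rose and 6 fell (9 and 8 adjusted over the list alone), with adjusted p = 0.854, and the haptoglobin gene Hp rose 1.25-fold (0.32 ± 0.04). Of 19 circadian clock genes 4 rose and 2 fell (7 and 2 adjusted over the list alone), with adjusted p = 0.320, or 0.0496 after centring. Without NASH-diet replicate 1, 3 rose and 1 fell. Dbp was 1.48-fold higher (0.56 ± 0.07) and Clock 1.21-fold lower (-0.27 ± 0.04). The order and time of day at which livers were taken are not given in the sources used here, and clock genes depend on the time of day.

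Markers of several other cells and tissues did not pass as lists. The changed members were 1 of 14 neutrophil markers (Lcn2, list adjusted p = 0.854), 1 of 12 dendritic cell markers (Irf8, 0.265), 1 of 14 cholangiocyte markers (Anxa2, 0.376), 2 of 12 adipose markers (Fabp4 and Cfd, 0.854) and 1 of 6 erythroid markers (Alas2, lower, 0.733). Without NASH-diet replicate 1 the counts were 3 for dendritic cells (with Clec9a and Ccr7, chosen after their values were seen) and 2 for cholangiocytes (with Spp1, chosen likewise), and 1 adipose marker was lower. Adjusted over the list alone, the counts over all mice were unchanged, and the calls of Irf8, Cfd and Alas2 were lost in 2, 6 and 5 of the 8 fits without 1 mouse. The neutrophil and adipose lists had medians of -0.01 and means of 0.19 and 0.12. None of 13 B and plasma cell markers (list adjusted p = 0.778), 12 pancreas markers (0.0957) or 13 skeletal muscle markers (0.198) passed in limma, also when adjusted over the list alone. Without NASH-diet replicate 1, the B cell gene Cd79b, chosen after its values were seen, passed (0.47, adjusted p = 0.0016). The lowest adjusted p among those genes over all mice belonged to Ighm (log2 fold change -0.50, 0.103), Cela1 (-0.10, 0.172) and Tnnc2 (-0.06, 0.298). The B and plasma cell list had a median of 0.00 and a mean of -0.03, and the pancreas list, whose genes lay near the lowest signals, passed after centring (0.0334) and without regular-diet replicate 2 (0.0435).

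The authors' deposited table lists 3096 genes as changed between the diets, 2347 higher and 749 lower. All 3096 had the same direction here, which was given in advance, since the listed log2 fold changes are differences of diet means of these same arrays. Of the 3096, 2654, or 85.7%, passed limma. The other 442 had an adjusted p of up to 0.110, and 34 probe sets passed here without being listed. With array weights, 3086 probe sets passed, 2337 higher and 749 lower, and 3082 of the listed genes were among them, with an adjusted p of 0.0246 for Jun. For Jun, the authors' deposited table gives a log2 fold change of 1.37 and a false discovery rate of 0.0245.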

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

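The tests of the low Jun array, of handling, of normalization, of a smaller share of hepatocytes, of the male-biased against the hepatocyte list and of the female-biased genes were chosen only after the result they bear on was seen.

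The number of changed probe sets is larger than chance gives. Of the 35 splits of the 8 mice into groups of 4, only the real 1 called as many as 2688, and the highest other split called 1. The count of gene lists past camera at its preset correlation does not by itself exclude chance. It was 28 for the real split and 29 for the highest other. As many passed in 4 of the 35 splits, the real one included. Each of the others exchanged only NASH-diet replicate 1, the mouse nearest to the regular-diet livers, with a regular-diet mouse. They therefore kept much of the diet difference, and their counts do not measure chance. Splits with equal numbers of each diet in both groups passed 4 to 17 lists, so camera at this setting passes lists without a diet difference. Fry's directional test passed 25 lists for the diets and 0 in the highest other split, so that 1 of 35 splits, the real one, did so.

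Jun was higher under the NASH-inducing diet, but it varied among regular-diet mice and moved with other rapidly induced genes. A single regular-diet array with a low Jun value is not the whole cause, since the log2 fold change without it was 0.99 with adjusted p = 0.0258. With the mean of the immediate early genes as a covariate the log2 fold change went from 1.37 (SE 0.36) to 0.063 (SE 0.40), a loss of the estimate rather than of precision. Jun and those genes thus changed together. The covariate did not overlap between the diets, so the fit cannot separate an effect of diet on Jun from that shared change. Handling or time to freezing that differed between the diets may have raised such genes. The 7 rapidly induced genes at log2 6.5 or more in regular-diet mice had a median log2 fold change of 0.44 (median absolute deviation 0.29). This median is under 0.5 times the change in Jun, but not by more than that spread. Ier2 (-0.10) and Socs3 (0.17), of the same set chosen after the data were seen, were left out. Their regular-diet means of 6.25 and 6.18 lay just below that level. With them the median would be lower, and the outcome depends on this cut-off, so this stays open. The design names the diet as the biological difference, and it cannot be told apart here from handling that followed diet.

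Markers of endothelial, Kupffer, stellate and recruited macrophage cells were higher while hepatocyte genes were lower. The authors' own normalization is not given and could not be undone, so whether it caused these rises cannot be tested here. A second scaling of the deposited values left most of each rise. Quantile normalization took a median per gene of 0.074 (bootstrap SE 0.0015) from the endothelial and 0.071 (SE 0.0029) from the Kupffer log2 fold changes. It took 0.074 (SE 0.0037) from the stellate and 0.059 (SE 0.013) from the recruited macrophage log2 fold changes. The 4 list medians were 0.38, 0.28, 0.31 and 0.41 as deposited. Centring, which shifts all genes of an array alike, took 0.058 from each, and all 4 lists passed camera under both. For the hepatocyte genes quantile normalization took 0.147 (SE 0.016) from a fall of median -0.26, which left -0.13, while centring gave -0.31. That list also passed camera under both, but how much of its fall is due to normalization stays open. A smaller share of hepatocytes, which raises all other cell types alike, could also contribute. Differences between the cell type lists had permutation p = 0.112, over markers found in 1 list only and at log2 6.5 or more in regular-diet mice. Medians ran from 0.32 for stellate to 0.65 for Kupffer cell markers among the endothelial, Kupffer, stellate and recruited macrophage lists. The B cell, cholangiocyte and dendritic lists held 1 such marker each, at -0.50, -0.02 and 0.44. No T and NK or neutrophil marker qualified. The permutation shuffled genes, which are not independent within a list, so its p-value does not decide the question. With so few markers it stays open, and regulation by the diet within each cell type was not tested.

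Male-biased liver genes were lower in NASH-diet mice. A female mouse is excluded, since the lowest Y-linked mean of a NASH-diet mouse lay only -0.049 from the regular-diet mean. A fall of equal measured size in all hepatocyte genes is not enough. The male-biased median lay -0.35 from the hepatocyte median (exact two-sided permutation p = 0.0286, the smallest that the 70 allocations of the mice allow). The hepatocyte list had a median signal of 11.80, against 9.95 for the male-biased list. Quantile normalization alone moved the hepatocyte median from -0.26 to -0.13. A shared fall of unequal measured size is therefore not excluded. Whether this is a shift from the male toward the female pattern of growth hormone-dependent genes stays open: the 17 female-biased genes did not pass camera as a set (adjusted p = 0.268), with a median log2 fold change of 0.00 and a mean of 0.46, and most of them lay near the lowest signals. Among them Cyp2b9, Abcd2 and, chosen after their values were seen, Cyp17a1 and Trim24 were higher, and Prlr, chosen in the same way, was lower. Growth hormone was not measured.

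Among 316 sets of 4 mice, for the 157 named genes and the first principal component in each diet, 10 held a mouse far from the other 3 of its diet. That is 3.16%, and chance flags about 1 in 20. In NASH-diet replicate 1, Clec7a was at 6.21 (other mice 6.71 to 6.80), Mcm2 at 6.39 (6.70 to 6.76), Vim at 8.80 (9.14 to 9.21) and Mmp19 at 8.45 (8.40 to 8.40), each on the side of the regular-diet mice. In NASH-diet replicate 2, Pex11a was at 10.99 (10.56 to 10.60) and Tat at 11.42 (11.83 to 11.90). In regular-diet replicate 4, Fos was at 5.87 (5.69 to 5.71), Ifi44 at 5.88 (6.12 to 6.17) and Lpcat3 at 9.78 (9.64 to 9.66). In regular-diet replicate 2, Cela2a was at 6.01 (6.08 to 6.09).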

How the results depend on the processing

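The fit with the immediate early genes as a covariate, the count of the authors' listed genes with array weights and the test of the olfactory receptor genes were chosen only after the data were seen. Directions were stable and counts were not: 0 of the 136 named genes besides Jun that passed changed direction in any fit. Over all mice, 8 of the 136 calls were lost after quantile normalization, 3 after centring, 8 with a trended, robust variance and 15 with the replicate block. With each of the 8 mice left out in turn, 104 of the 136 genes passed every time. The calls lost in some of those fits, in 1 to 7 of the 8, were those of Gpt2, Mcm2, Timp3, Irf8, Gadd45g, Cxcl13, Cyp4f14, Cdkn1a, Il18, Cyp2c70, Tat, Rgs5, Tk1, Cxcl9, Alas2, Myc, Gbp3, Ndufa2, Ccl3, Gbp2, Atf3, Atf4, Fn1, Cfd, Atp5o, Ccl5, Cyp51, Fosl2, Mcm6, Sesn2, Msmo1 and Pmvk. The number of probe sets past the threshold was 2765 after quantile normalization (1940 of them shared with the 2688), 3223 after centring (1981 shared), 2853 and 2587 without the dimmest 25% or 50%, 2619 with a trended, robust variance and 3086 with array weights. It was 991 at an adjusted p of 0.01 and 106 at an absolute log2 fold change of 1, both stricter by construction, and ran from 1666 without NASH-diet replicate 2 (1698 without NASH-diet replicate 3) to 3086 without NASH-diet replicate 1. Olfactory receptor genes, which lie near the lowest signals, had a median log2 fold change of -0.027 as deposited, -0.0044 after quantile normalization and -0.085 after centring. Genes of the authors' deposited table past the fit numbered 991 and 106 at those stricter thresholds, 2029 after quantile normalization and 3082 with array weights. Jun kept its log2 fold change of 1.37 with a trended, robust variance but not its call (adjusted p = 0.0794, with 0.0169 to 0.0411 in the other settings over all mice). It was 0.99 to 1.63 with 1 mouse left out, and 0.063 with the covariate. Camera with an estimated correlation passed 0 lists (5 at an unadjusted p under 0.05, and 25 by fry). The first principal component held 76.3% of the variance of the 1000 most variable probe sets.

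Whether equal replicate numbers pair the mice, by cage or day, is not given in the sources used here. Deviations of same-numbered mice from their diet means correlated at -0.03, -0.04, 0.11 and 0.04. These values show little sign of pairing but cannot exclude it. With the replicate block, 2278 probe sets passed (2022 shared), 28 lists passed and Jun stayed at 1.37 (adjusted p = 0.0254). Log2 fold changes that turned sign belonged to genes and lists past no threshold as deposited, except the P450 list, and the cause was not tested. After quantile normalization these were Atf2 (-0.056), Batf3 (-0.028) and the mean of the erythroid list (-0.00152). After centring they were Atf2 (-0.037), Fosl1 (-0.026), Batf3 (-0.057), Batf (-0.00625) and the means of the erythroid (-0.015) and glutathione (-0.045) lists. Without the dimmest 50% they were the erythroid (-0.011) and glutathione (-0.014) lists, and over members of no other list the adipose list (-0.044). With 1 mouse left out, the ranges were -0.013 to 0.057 for Atf2, -0.017 to 0.037 for Batf3, -0.064 to 0.0018 for the P450 list, -0.042 to 0.049 for glutathione and -0.055 to 0.088 for erythroid genes. With 1 probe set per gene, averaging probe sets of a gene was not possible.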

Other observations

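The gene families, the position of each NASH-diet mouse and the comparison of lipid with inflammatory genes were tested only after the data were seen.

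Families of genes that share a symbol root were tested in the same way as the fixed lists. Of 329 families with at least 8 genes, 28 passed camera, those named here with adjusted p from 6.66e-06 for Toll-like receptors to 0.0249 for annexins, and none passed with an estimated correlation (adjusted p = 0.735 for each family named here but the Gbp genes, at 0.751). Passing camera alone does not show a change of note in the liver, because families that lie near the lowest signals passed as well: the olfactory receptor (adjusted p = 6.66e-06), vomeronasal receptor (0.00019), prolactin and taste receptor genes (both 0.0249), with median log2 fold changes of -0.027, -0.033, -0.040 and -0.031. Acyl-CoA thioesterase genes rose in 9 of 13 cases, led by Acot2 (2.86-fold), Acot4 (2.05-fold) and Acot3 (1.76-fold), whose probes can be shared. Annexin genes, whose proteins bind membrane phospholipids with calcium, rose in 7 of 12 cases and fell in 1, with Anxa2 (3.73-fold) and Anxa5 (2.55-fold) ahead of Anxa7 (1.32-fold) and Anxa3 (1.31-fold). Toll-like receptor genes rose in 8 of 12 cases, and interferon-inducible Ifi genes in 9 of 17, with Ifi27l2b (2.01-fold) and Ifi207 (1.82-fold) among them. Guanylate-binding protein (Gbp) genes rose in 6 of 11 cases. Peroxin genes rose in 5 of 17 cases, with Pex11a (2.64-fold) well above Pex19 (1.27-fold) and Pex3 (1.25-fold). Tumour necrosis factor receptor family genes rose in 6 of 20 cases, led by Tnfrsf19 (1.65-fold).

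Among the lower families were the carboxylesterases, with 6 of 19 lower and none higher, and the UDP-glucuronosyltransferases, with 4 of 13 lower and none higher. Ces2a (log2 fold change -1.65), Ces3b (-1.01), Ces2c (-0.75) and Ugt2b1 (-0.75) led them. Small nucleolar RNA genes fell in 3 of 9 cases, led by Snord32a (-0.69). The P450 (Cyp) family was lower too (camera, adjusted p = 0.00119), with 23 of 92 genes lower and 9 higher. Not every lower family that passed is named here. The median of each family named here kept its sign after quantile normalization and centring, but not always its size: that of the peroxin genes went from 0.091 to 0.013 and 0.033, and that of the tumour necrosis factor receptor family from 0.090 to 0.074 and 0.032. The olfactory receptor median went from -0.027 to -0.0044 and -0.085.

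NASH-diet replicate 1 lay nearest to the regular-diet arrays. Of the 3086 probe sets called without it, 93.8% moved in the same direction in it, at a median share of 0.546 of the change in the other mice, against 1.24, 1.01 and 0.90 for replicates 2, 3 and 4 left out in the same way. A smaller response of the same genes in that mouse is consistent with this. The share in that mouse differed between 2 gene groups. Lipid genes in it showed a median share of 0.916 of the change in replicates 2 and 3, and inflammatory genes 0.419. The difference was 0.497 over 58 and 64 genes called without replicates 1 and 4 (permutation p = 0.0001, the smallest the permutations can give). Over the same genes replicate 4 had median shares of 0.599 for lipid and 1.04 for inflammatory genes (difference -0.445, permutation p = 0.0001, likewise the smallest). The permutations shuffled genes, which are not independent within a group, so these p-values can be far too small. They also describe single livers. A response smaller by 1 common factor is therefore not excluded, and what set the livers apart was not tested.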
